A study of Mus musculus with 4 samples.

How the data were processed

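Live T cells sorted by flow cytometry from tumour-draining lymph nodes of MC38-OVA-bearing mice were sequenced as 4 single-cell 5' libraries, 1 for each combination of genotype label (control or dendritic-cell-conditional Cd274 knockout) and treatment (control or doxorubicin). The deposited values are counts of UMIs for each gene and barcode, and the genome build is mm10 per the submitters' processing notes. The alignment and cell calling tools and their settings are not given in the sources used here. The least deep barcode held 500 UMIs. Gene positions and transcript lengths were taken from GENCODE M21 for GRCm38, which covers 32158 of the 32285 gene identifiers.

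Of 48597 barcodes, 48578 with at least 300 genes and at most 10% mitochondrial UMIs were kept. Only 2, 2, 1 and 0 barcodes in WT-CTRL, WT-DOX, KO-CTRL and KO-DOX passed 10%, so this limit removed almost no cells. Scrublet scores were computed in each library, and its automatic threshold marked 0 cells, so a fixed score above 0.25 was used instead, a choice made after that was seen. It removed 1059 cells (1.98%, 2.86%, 1.91% and 1.95% in WT-CTRL, WT-DOX, KO-CTRL and KO-DOX). Of 214 cells with at least 2 UMIs of Cd4 and 2 of Cd8a and Cd8b1 together, 25.2% scored above it, so some doublets stayed. The cells were normalised to 10000 counts, and the libraries were clustered together on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, Python 3.11.15). The principal components were recomputed in double precision after first results had been seen, because single precision moved cluster borders between machines. Each of the 17 clusters took its name from fixed marker sets and kept a number where these did not decide. T-like cells are all clusters except the B- or plasma-like cluster and cluster 15.

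UMIs were summed over the T-like cells of each library, and over 5 classes with at least 200 cells in each library: naive CD4-like, clusters 5 and 8, effector or memory CD8-like, Treg-like and Tfh-like. They were divided by the library's total in the same cells to give CPM, with exact Poisson 95% intervals. The log2 fold is that of CPM plus 1. Shares of cells have exact Clopper-Pearson 95% intervals, and share ratios a 95% interval from the same counts. All intervals cover counting error only. Where the intervals of both levels overlap, the interval of their ratio can still leave out 1. With 1 library in each group no test between groups exists, so no p is given. The comparisons were WT-DOX against WT-CTRL, KO-DOX against KO-CTRL, KO-CTRL against WT-CTRL and KO-DOX against WT-DOX, and the difference of the doxorubicin responses. The number of mice in a library is not given.

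Lists of genes, 23 in all, were written from general knowledge: naive and quiescence, early T cell receptor response, cytotoxic, inhibitory receptor and exhaustion, memory and activated, regulatory, helper cytokine, follicular helper, type I interferon, interferon gamma, p53 target, DNA repair, S phase, G2 and M phase, heat shock and dissociation stress, ferroptosis with iron and oxidative stress, integrated stress, apoptosis, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded, migration and PD-1 pathway with co-stimulation. Mx1, Mx2 and P2ry8 were absent from the gene table. For each list the median log2 fold over members with a mean of at least 5 CPM was set beside 10000 random lists matched for level in 20 bins, as a description. Counts of members at least 0.32 log2 units apart follow a rule of size. On simulated data all 200 genes altered by 0.32 log2 units or more were recovered, 2.59% of 7466 unaltered genes had intervals apart, and 4% of random lists fell outside the central 95%. The simulation drew independent Poisson counts for each gene, without variation between cells or mice. Its rates therefore check the calculation and are not error rates for these libraries.

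The genes named were set by rule: over T-like cells with at least 10 CPM in either library, the 8 with the largest log2 fold in each direction whose intervals were apart; within each class with at least 50 CPM and 50 UMIs, the 4 largest in each direction; the largest members of each list, up to 2 in each direction; the 6 largest response differences in each direction; and Cd274, Pdcd1, Ifng, Gzmb, Foxp3, Mki67, Cd4 and Cd8a. Some genes that this rule picks are not reported here. The class values of Bbc3 and the T-like values of Rps29, Rps28 and Rpl38 were chosen after they were seen. The groups, comparisons, lists and this rule, and the alternatives not said to be added, were fixed before the data were examined.

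The alternatives were Leiden resolutions 0.5 and 2, 1000 variable genes, doublets kept, a stricter filter of 800 genes and 5% mitochondrial UMIs, CD8 and CD4 cells by marker UMIs, median-of-ratios scaling (which moved no library by more than 0.014 log2), each cell at the same weight, a pseudocount of 5, T classes at equal proportions, list members above 20 CPM or with any UMI, and cells thinned to 1500 UMIs. Added after seeing the data were clustering without interferon and heat shock genes, other random seeds, and leaving out cells with both Cd4 and Cd8 UMIs, the cycling-like cluster, or clusters 0 to 2. The cycling-like, interferon-stimulated-like and gamma delta T-like clusters had fewer than 200 cells in at least 1 library and were not compared gene by gene.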

Results

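T cells sorted from the tumour-draining lymph nodes of mice carrying MC38-OVA tumours, a mouse colon carcinoma line made to express ovalbumin, were profiled by droplet single-cell RNA sequencing with a 5' kit. The mice were labelled either as control genotype (WT) or as conditional knockout of Cd274, which encodes PD-L1, in dendritic cells (KO), a difference that the Cd274 counts given at the end do not show, and they received either doxorubicin, an anthracycline that damages DNA, or the control treatment (CTRL). This gave 4 libraries, 1 for each group, named WT-CTRL, WT-DOX, KO-CTRL and KO-DOX, and the number of mice pooled in each is not given. There are no replicates, so every interval covers counting error only and no difference could be set against the spread between mice. The libraries held 12828, 12438, 12959 and 10372 barcodes in that order, with 46300824, 42987683, 47081849 and 37754389 unique molecular identifiers (UMIs), each UMI being 1 counted transcript. After filtering, 12488, 12016, 12623 and 10079 T-like cells entered the comparisons, with median depths of 3048.5, 2971, 3015 and 2973 UMIs.

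Naive CD4-like cells and CD8-like cells with little Ccl5 made up much of each library. Naive CD4-like cells join clusters 3 and 10, with Cd4 at 165 and 166 CPM. Igfbp4 was among the leading genes of both, but Cd40lg only of cluster 10. Naive CD4-like cells formed 28.1% of T-like cells in WT-CTRL, 28.8% in WT-DOX, 27.7% in KO-CTRL and 28.4% in KO-DOX. CD8-like cells of clusters 5 and 8, marked by Cd8a, Cd8b1 and Dapl1 with little Ccl5, formed 25.3%, 26.3%, 22.2% and 28.5%. These are not all naive, since the leading genes of cluster 5 include more effector or memory markers (4) than markers of its own (2). Effector or memory CD8-like cells, led by Ccl5, Ly6c2 and Xcl1, took 3.88%, 4.54%, 3.91% and 4.47%. Cells resembling follicular helper T cells (Tfh), the CD4 cells that help B cells, were led by Sostdc1, Tox2 and Il21 and took 5.08%, 4.73%, 6.54% and 8.17%. This Tfh-like cluster is counted as CD4-like throughout but also held CD8 cells. Its Cd8a stood at 163 CPM and its Cd8b1 at 227 CPM, against 193 and 562 CPM in effector or memory CD8-like cells. Values within it can therefore shift with its fraction of CD8 cells, which was not tested. Treg-like cells, led by the regulatory T cell factor Foxp3, took 3.43%, 3.09%, 3.87% and 3.87%, and cycling-like cells 1.71%, 1.37%, 2.07% and 2.37%. Clusters 0, 1, 2, 6 and 9 remained unnamed, because mitochondrial, nuclear or immediate early transcripts or a mixed set led them. Clusters 2 and 9 still carried CD8 transcripts, with Cd8b1 at 839 and 793 CPM and Cd4 at 3.47 and 5.54 CPM. They are left out of the CD8-like shares. Cluster 1 carried Cd4 at 120 CPM and Cd8b1 at 135.5 CPM, and is left out of the CD4-like shares. Shares of CD4-like cells therefore refer to an incomplete total.

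**Figure D1:**
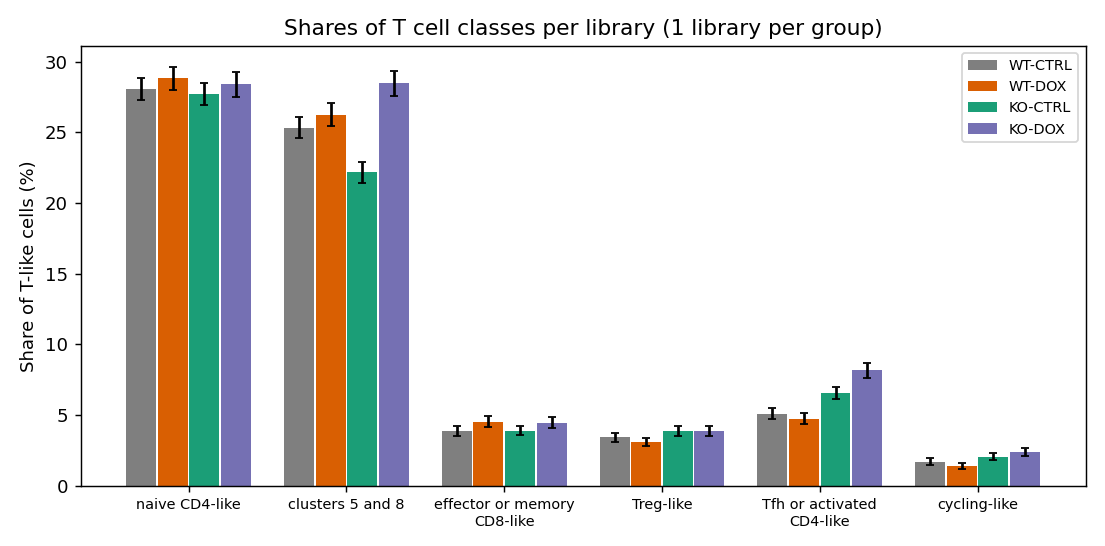
Share of T-like cells in each class (percent, with exact 95% intervals) for the 4 libraries. The Tfh-like share ranges from 4.73% in WT-DOX to 8.17% in KO-DOX, while the naive CD4-like share stays between 27.7% and 28.8%.

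WT-DOX against WT-CTRL asks how the nodal T cells differ with doxorubicin in the control genotype. Some targets of p53, the factor that answers DNA damage, were higher in WT-DOX, while cell division, type I interferon and activation genes were lower. Bbc3, which encodes the death-promoting protein PUMA, stood at 48.0 CPM, UMI counts scaled to a common library total, with a 95% interval of 45.9 to 50.2, against 23.0 CPM (21.6 to 24.5), and was higher in all 5 T cell classes examined: 67.9 against 30.3 CPM in naive CD4-like cells and 84.4 against 44.2 CPM in effector or memory CD8-like cells, for example. Ddit4, a stress gene that restrains growth signalling, stood at 42.4 against 24.6 CPM. Over 26 measured p53 targets the median log2 fold was 0.097, with 4 higher and 1 lower by at least 0.32 log2 units, the size from which list members are counted throughout. It was 0.29 in Treg-like and 0.25 in Tfh-like cells, where 12 of 29 and 9 of 26 targets were higher. The medians in effector or memory CD8-like cells (0.12), clusters 5 and 8 (0.061) and naive CD4-like cells (0.028) lay inside the central 95% of random gene lists matched for level. Apoptosis regulators as a list had a median of -0.034, though Bcl2, which opposes PUMA, was higher at 174 against 133 CPM.

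Division transcripts were lower in WT-DOX: 21 of 36 G2 and M phase genes passed that size, with a median log2 fold of -0.43. Mki67, the usual proliferation marker, stood at 49.3 against 78.2 CPM and Top2a, the topoisomerase that doxorubicin poisons, at 72.3 against 106 CPM. Cycling-like cells were 0.805 times as frequent (95% interval 0.658 to 0.985), although the intervals of the shares themselves overlapped, and with the T classes weighted to equal proportions the G2 and M phase median shrank to -0.14. The S phase median of -0.16 turned to 0.019 under the same weighting. Core histone genes led the lower genes. Hist1h2bg stood at 5.26 against 16.01 CPM, but 1 cell gave 204 of its WT-CTRL UMIs and the log2 fold of -1.44 was -0.18 without the cycling-like cluster.

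Type I interferon response genes were lower in WT-DOX (median -0.21, 7 of 35 lower and none higher), and the direction was the same in each of the 5 classes, with medians from -0.14 to -0.19, and -0.13 over all at equal class proportions. Ifi27l2a stood at 406 against 574 CPM and Ifit3 at 10.6 against 15.2 CPM. Lists of activated T cells were also lower, among them follicular helper genes (-0.18), memory and activated genes (-0.16), PD-1 pathway and co-stimulation genes (-0.16), regulatory genes (-0.14) and inhibitory receptors (-0.11). Maf, a factor of Tfh and other effector CD4 cells, stood at 31.3 against 48.6 CPM, Cd200 at 18.7 against 28.9 CPM and the checkpoint receptor Lag3 at 9.71 against 14.9 CPM. These lists depended on the class mix: at equal class proportions the medians were -0.046 for follicular helper, -0.0079 for memory, -0.066 for PD-1 pathway, -0.0048 for regulatory and 0.0066 for inhibitory receptor genes, all inside the random range, and the early T cell receptor response median, -0.097 as measured, was 5.2e-05. The Tfh-like share itself was not separable between these libraries (ratio 0.931, interval 0.834 to 1.04). Il7r, the receptor for the survival cytokine interleukin 7, was higher at 554 against 384 CPM, and Ccl5 at 211 against 156 CPM, while S1pr1, the receptor that lets T cells leave lymph nodes, was lower at 280 against 356 CPM.

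Among single genes of WT-DOX against WT-CTRL, Zbed5, a gene derived from a transposase, stood at 261 CPM in WT-DOX and at 1.05 CPM in WT-CTRL, 0.838 CPM in KO-CTRL and 1.02 CPM in KO-DOX. It lies on chromosome 5 of mm10, 129895723 to 129903623, and was found in 5860 WT-DOX cells, in each of the 5 classes. Cdk5rap1 (37.5 against 11.4 CPM), Ehbp1 (78.1 against 25.5 CPM), Hnrnpa0 (97.9 against 55.4 CPM), Adamts13 and Ly6k were also higher, and the first 3 of these were lower in WT-CTRL than in any other library. Of 41 ribosomal protein genes with transcripts under 700 nt, 4 were lower in WT-DOX, all under 400 nt, while the median of the 41 was 0.058. Rps27rt stood at 239 against 480 CPM, Rps29 at 2320 against 3951 CPM, Rps28 at 2206 against 3220 CPM and Rpl38 at 2115 against 3041 CPM. Anks1b and Wdr89 were lower as well. Heat shock and dissociation stress genes (0.11) and nuclear oxidative phosphorylation genes (0.073) were slightly higher. Smaller negative medians fell to DNA repair genes (-0.095), helper cytokines (-0.093, but 0.041 at equal class proportions), mitochondrially encoded genes (-0.10, but -0.0092 without clusters 0 to 2) and migration receptors (-0.057). Those of helper cytokines and migration receptors lay inside their random ranges. Naive (0.037), integrated stress (0.039), glycolysis (-0.033), interferon gamma (-0.024), cytotoxic (-0.0093) and ferroptosis (0.0013) lists had medians near 0. Cd274, Pdcd1, Ifng and Foxp3 had overlapping intervals, whereas Gzmb (24.1 against 34.7 CPM) and Cd4 (75.8 against 92.2 CPM) were lower and Cd8a was higher (210 against 191 CPM).

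KO-DOX against KO-CTRL puts the same treatment question to mice with the knockout label. Tfh-like cells, Tfh genes and Pdcd1 were higher in KO-DOX, p53 targets were slightly higher by median, and interferon-stimulated and mitochondrially encoded genes were lower. Tfh-like cells formed 8.17% (7.64% to 8.72%) against 6.54% (6.12% to 6.99%) of T-like cells, a ratio of 1.248 (1.14 to 1.37), and 20.2% against 17.2% of CD4-like cells. Tox2, a factor that promotes Tfh development, stood at 32.5 against 19.9 CPM, Sostdc1, a secreted inhibitor made by a subset of Tfh cells, at 40.6 against 23.3 CPM, and the inhibitory receptor Tigit at 75.5 against 50.5 CPM. Pdcd1, which encodes the PD-L1 receptor PD-1, stood at 23.2 against 17.8 CPM, at 141 against 111 CPM within Tfh-like cells and at 53.4 against 27.5 CPM within Treg-like cells. Within Tfh-like cells the follicular helper list had a median of 0.22, with 7 of 17 members higher. In Treg-like cells the tissue repair factor Areg stood at 607 against 262 CPM, found in 104 KO-DOX cells with up to 104 UMIs in 1 of them, and the decoy receptor Il1r2 at 208 against 104 CPM.

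The p53 targets had a median of 0.12 in KO-DOX against KO-CTRL, with 1 of 26 higher by the size counted. The median was 0.23 in Treg-like and 0.22 in Tfh-like cells, but -0.042 in naive CD4-like cells, 0.032 in clusters 5 and 8 and 0.048 in effector or memory CD8-like cells, all 3 inside the random range. Ddit4 stood at 50.7 against 35.5 CPM and Bax, a direct effector of cell death, at 134 against 117 CPM. The apoptosis (0.11), integrated stress (0.10), cytotoxic (0.12) and regulatory (0.11) lists had small positive medians. Without clusters 0 to 2, however, the integrated stress median was -0.0042, and the apoptosis, cytotoxic and regulatory medians shrank while staying positive. Follicular helper (0.16), inhibitory receptor (0.082), memory (0.080) and oxidative phosphorylation (0.063) medians were positive as well, but those of inhibitory receptor and memory genes were 0.0044 and 0.014 without clusters 0 to 2. The PD-1 pathway median of 0.040 lay inside its random range and was -0.0073 at equal class proportions. G2 and M phase (0.014), S phase (0.0095), DNA repair (-0.0061), glycolysis (0.028), helper cytokine (0.028), migration (0.026), interferon gamma (-0.0075) and ferroptosis (0.0077) lists had medians inside their random ranges. Naive (-0.027), early T cell receptor response (-0.044) and heat shock (-0.032) medians were small but below theirs. Of these, the naive and early T cell receptor medians turned to 0.0041 and 0.024 when each cell had the same weight.

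Type I interferon genes were lower in KO-DOX (median -0.29, 15 of 35 lower and none higher), but by a median of -0.14 with 6 of 35 lower at equal class proportions, a weighting in which interferon-stimulated-like cells are a class of their own. Ifit3 stood at 16.4 against 42.6 CPM, Ifit1 at 18.99 against 43.0 CPM and the antiviral gene Rsad2 at 3.77 against 10.8 CPM. The median was -0.23 in Tfh-like and -0.16 in Treg-like cells but -0.039 in naive CD4-like cells, 0.019 in clusters 5 and 8 and 0.045 in effector or memory CD8-like cells. The interferon-stimulated-like cluster held 213 cells in KO-DOX and 590 in KO-CTRL. All 11 mitochondrially encoded genes were lower in KO-DOX by that size (median -0.53), and their median was negative in each class, from -0.23 in Treg-like cells to -0.61 in clusters 5 and 8. mt-Nd4 stood at 30.04 against 46.9 CPM. Mitochondrial transcripts were scarce everywhere, with a median share per cell of 0.064%, 0.056%, 0.060% and 0.032% of UMIs in WT-CTRL, WT-DOX, KO-CTRL and KO-DOX. These folds thus compare very low levels. CD8-like cells of clusters 5 and 8 were 1.29 times as frequent in KO-DOX, and all CD4-like cells 1.06 times, a direction that turned to 0.937 under the stricter cell filter. Cluster 1, led by nuclear transcripts, carried Cd4 at 120 CPM but is not counted as CD4-like. Its share fell from 11.9% to 6.55% of T-like cells (ratio 0.550), which raises the other shares by construction. The CD4-like ratio of 1.06 thus depends on leaving this cluster out. Setbp1, a chromatin gene on chromosome 18, led the higher genes at 25.6 against 5.20 CPM, followed by Adamts13 at 28.1 against 10.8 CPM. The peptide transporter Slc15a2 was also higher at 103 against 67.9 CPM.

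KO-CTRL against WT-CTRL compares the genotype labels without doxorubicin. Interferon-stimulated genes and Tfh-like cells were higher in the library labelled KO-CTRL. Type I interferon genes had a median of 0.43, with 23 of 35 higher and none lower. Ifit3 stood at 42.6 against 15.2 CPM and Rsad2 at 10.8 against 3.70 CPM, Ly6a, an interferon-inducible surface protein, at 183 against 128 CPM, and the interferon-induced GTPase gene Iigp1 at 39.4 against 20.6 CPM. The interferon gamma list had a median of 0.16. Interferon-stimulated-like cells were 2.92 times as frequent in KO-CTRL as in WT-CTRL (interval 2.49 to 3.42). The type I interferon median was 0.37 in Treg-like, 0.26 in Tfh-like and 0.21 in naive CD4-like cells, but 0.076 in effector or memory CD8-like cells and 0.081 in clusters 5 and 8, and 0.21 at equal class proportions, a weighting that removes part of any interferon difference because interferon-stimulated-like cells form a class of their own.

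Tfh-like cells were 1.29 times as frequent in KO-CTRL as in WT-CTRL (interval 1.17 to 1.43). The follicular helper list over all T-like cells had a median of 0.047, inside its random range. Sostdc1 stood at 23.3 against 13.02 CPM and Pdcd1 at 17.8 against 14.2 CPM. The granzyme gene Gzmk, typical of early effector and memory CD8 cells, stood at 12.7 against 6.28 CPM and the chemokine gene Ccl4 at 17 against 10.2 CPM. In effector or memory CD8-like cells the natural killer receptor gene Klra7 was lower at 28.0 against 72.8 CPM, with Klrc1, Klre1 and Fcer1g. In Treg-like cells Gzmb stood at 152 against 264 CPM and the suppressive cytokine gene Il10 at 44.4 against 87.8 CPM. Bbc3 was higher in KO-CTRL too, at 33.2 against 23.0 CPM, and the p53 list had a median of 0.071, above its random range. Penk, which encodes an opioid precursor, stood at 17.5 against 8.18 CPM from 83 and 49 cells, with 122 UMIs in 1 cell. CD8-like cells of clusters 5 and 8 were 0.875 times as frequent.

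Division genes gave no stable direction between KO-CTRL and WT-CTRL. The G2 and M phase median of 0.18 was -0.031 at equal class proportions and -0.069 without the cycling-like cluster, the S phase median of 0.16 was -0.030 when each cell had the same weight, and Mki67 (88.3 against 78.2 CPM) had a log2 fold of 0.17 that turned to -0.33 with each cell at the same weight. The memory median of 0.067 was -0.050 at equal class proportions. Naive genes (-0.10), mitochondrially encoded genes (-0.13, but -0.0090 at equal class proportions), migration receptors (-0.080) and early T cell receptor response genes (-0.054) had small negative medians, and Dapl1, a marker of naive and memory CD8 cells, stood at 171 against 223 CPM. Small positive medians belonged to oxidative phosphorylation (0.087), glycolysis (0.073), apoptosis (0.060), heat shock (0.051), DNA repair (0.050), inhibitory receptors (0.048), cytotoxic (0.046), helper cytokine (0.029) and ferroptosis (0.026) lists. Of these, the heat shock, inhibitory receptor, cytotoxic, helper cytokine and ferroptosis medians lay inside their random ranges. Several of the positive medians turned: DNA repair and glycolysis to -0.029 and -0.0058 with each cell at the same weight, and inhibitory receptor, helper cytokine and cytotoxic genes to -0.073, -0.015 and -0.0013 at equal class proportions. Regulatory (0.0064), integrated stress (-0.0094) and PD-1 pathway (-0.015) lists were close to 0, but the regulatory median was -0.11 at equal class proportions, below its random range. Cdk5rap1 (28.8 against 11.4 CPM), Hnrnpa0 (130 against 55.4 CPM) and Ehbp1 (51.2 against 25.5 CPM) led the higher genes beside the interferon genes, and Mbd2, which encodes a protein that binds methylated DNA, stood at 131 against 65.1 CPM in clusters 5 and 8. Slc15a2 (67.9 against 106 CPM), Tiam2, Auts2, Wdr89 and Rps27rt (344 against 480 CPM) were lower.

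KO-DOX against WT-DOX compares the genotype labels under doxorubicin. The library labelled KO-DOX held more Tfh-like and cycling-like cells and higher inhibitory receptor, division and interferon genes. Tfh-like cells were 1.73 times as frequent (interval 1.56 to 1.92) and cycling-like cells 1.73 times (1.42 to 2.10). Treg-like cells were 1.253 times as frequent (1.09 to 1.44) among T-like cells, but their share of CD4-like cells (ratio 1.14) had overlapping intervals. The follicular helper list had a median of 0.55, with 10 of 14 members higher, and 0.25 at equal class proportions. Within Tfh-like cells the same list had a median of 0.26, and Sostdc1 stood at 371 against 164 CPM. Tigit stood at 75.5 against 40.3 CPM, Tox2 at 32.5 against 17.5 CPM, Il21, the main Tfh cytokine, at 13.2 against 7.54 CPM, and Pdcd1 at 23.2 against 12.5 CPM. Pdcd1 had a log2 fold of 0.84 over all T-like cells and 0.37 at equal class proportions, and was higher inside Tfh-like (141 against 96.2 CPM) and Treg-like cells (53.4 against 28.0 CPM). Il2, the T cell growth factor, was lower in Tfh-like cells at 37.2 against 77.5 CPM, as was Cd8a at 137 against 233 CPM. A smaller fraction of CD8 cells in this cluster could thus add to its other differences, and was not tested.

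The G2 and M phase median was 0.66, with 29 of 36 genes higher, and the S phase median 0.31. Mki67 stood at 85.3 against 49.3 CPM and Rrm2, which supplies nucleotides for replication, at 61.2 against 37.3 CPM. The medians shrank to 0.064 and 0.0023 at equal class proportions, the first still above its random range, and to 0.058 and 0.053 without the cycling-like cluster. Within Tfh-like cells they were 0.19 and 0.14, while the G2 and M phase median was -0.32 in Treg-like cells. Inhibitory receptors (0.32, or 0.11 at equal proportions), PD-1 pathway genes (0.29, or 0.042), regulatory genes (0.26, or -0.012) and memory genes (0.23, or -0.031) also depended on the mix. So did the smaller positive medians of glycolysis (0.18, or 0.074), cytotoxic (0.14, or 0.016), DNA repair (0.11, or 0.036), migration (0.10, or 0.013), oxidative phosphorylation (0.098, or 0.020) and helper cytokine genes (0.096, or -0.037). The apoptosis (0.074, or 0.051), ferroptosis (0.049, or -0.0045), p53 (0.029) and integrated stress (0.0058) medians were nearer 0. As measured, these and the helper cytokine median lay inside their random ranges. The heat shock (-0.13, or -0.048) and naive (-0.090, or -0.00068) medians were negative, and the early T cell receptor median of -0.046 turned to 0.014 with members above 20 CPM only. Jun (483 against 618 CPM), Zfp36 (394 against 552 CPM) and Bbc3 (37.8 against 48.0 CPM) were lower in KO-DOX.

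Type I interferon genes were higher in KO-DOX than in WT-DOX (median 0.30, 14 of 35 higher and none lower), in every class examined, with medians from 0.16 in Tfh-like to 0.34 in naive CD4-like cells, and 0.19 over all at equal class proportions. Ly6a stood at 200 against 112 CPM, and at 88.6 against 41.8 CPM in clusters 5 and 8. Iigp1 stood at 34.5 against 18.4 CPM, and the interferon gamma list had a median of 0.14. The chemokine receptor gene Cxcr3 stood at 26.7 against 16.04 CPM, Ifng at 22.7 against 14.8 CPM and Gzmk at 15.6 against 6.25 CPM. All 11 mitochondrially encoded genes, scarce in every library, were lower by the same size (median -0.61). mt-Cytb stood at 145 against 224 CPM. Setbp1 (25.6 against 6.38 CPM), Gpm6b and Plcb4 were higher, Zbed5 was lower (1.02 against 261 CPM), and Ier3, a stress gene induced by NF-kB, was lower at 5.50 against 11.3 CPM. In Treg-like cells Penk stood at 148 against 29.4 CPM and Igfbp4, typical of naive-like cells, at 48.5 against 129 CPM.

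**Figure D2:**
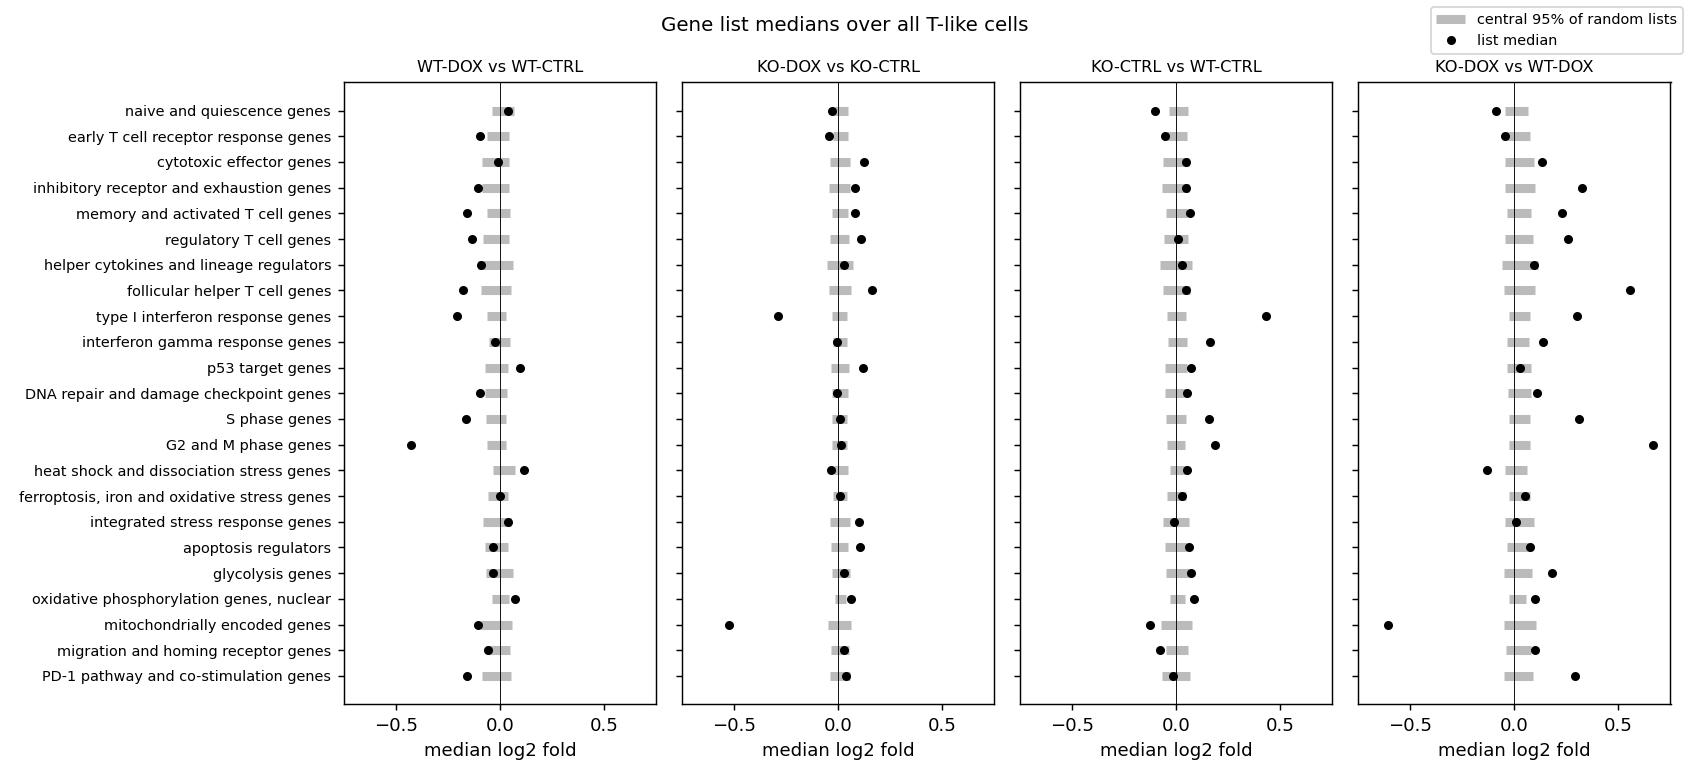
Median log2 fold of each gene list over T-like cells in the 4 comparisons, with the central 95% of matched random lists. Type I interferon genes lie at -0.21 and -0.29 in the doxorubicin comparisons and at 0.43 and 0.30 in the genotype comparisons.

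The difference between the doxorubicin responses, KO minus WT in log2 units, was largest for Setbp1 (2.21) and core histone genes such as Hist1h2bn (1.35), and most negative for Zbed5 (-6.86), Ehbp1 (-1.21), Rsad2 (-1.09) and Hnrnpa0 (-1.08). It is a value from 4 single libraries and was not tested. Over the whole transcriptome the libraries were close: across 3159 genes above 50 CPM, which are not independent replicates, log CPM of KO-DOX and KO-CTRL had a Pearson r of 0.998, KO-CTRL and WT-CTRL 0.996, and WT-DOX 0.990 with each of the others. The median absolute log2 difference was smallest between KO-DOX and KO-CTRL (0.048) and largest between KO-DOX and WT-CTRL (0.087), so the measures order the libraries differently. By this median KO-CTRL was as close to WT-DOX (0.065) as to WT-CTRL (0.065). A gene as far apart as Zbed5 can lower r, and r without it was not computed.

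**Figure D3:**
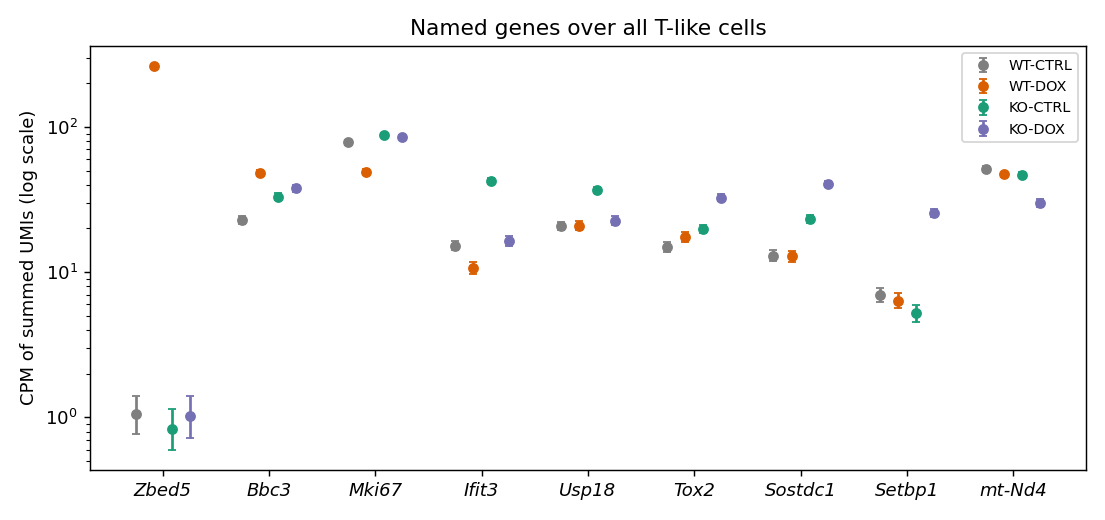
Level of selected genes in T-like cells (CPM, log axis, exact 95% intervals) in the 4 libraries. Bbc3 goes from 23.0 CPM in WT-CTRL to 48.0 CPM in WT-DOX, and Tox2 is highest in KO-DOX at 32.5 CPM.

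The genotype labels were checked through Cd274. The leading genes of cluster 15 include the dendritic cell markers Fscn1 and Cst3, and H2-Aa, H2-Eb1, H2-Ab1 and Cd74 from the fixed B cell set. The B cell marker Cd79a stood at 0 CPM there, against 1583 CPM in the B- or plasma-like cluster. In cluster 15 Cd274 stood at 359 CPM (282 to 452) in WT-CTRL, 400 CPM (280 to 554) in WT-DOX, 672 CPM (523 to 851) in KO-CTRL and 395 CPM (308 to 500) in KO-DOX, from 27, 21, 17 and 25 cells. It was not lower in the libraries labelled KO. The sorting left few such cells, which part of the gene is deleted is not given, and 5' counting may still count a transcript of a recombined gene. In T-like cells, which the knockout does not target, Cd274 stood at 83.6 CPM in KO-CTRL against 66.8 CPM in WT-CTRL and at 82.5 CPM in KO-DOX against 65.7 CPM in WT-DOX.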

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

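The tests of the mix of T cell classes and of doublets were chosen only after the result was seen, while the other tests were written before. How the count of neighbouring genes and the doublet test are read was amended after their results were seen, which left both undecided; as first written, the doublet test argued against doublets. The pairs of effects set against each other first are differences between single libraries that were not tested.

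Activated T cell genes went opposite ways with doxorubicin in the genotypes. The follicular helper list had a median log2 fold of -0.18 with the control genotype and 0.16 with the knockout label, a difference of 0.34. The same difference was 0.24 for regulatory T cell genes (-0.14 and 0.11), 0.24 for memory and activated genes (-0.16 and 0.080) and 0.19 for inhibitory receptors (-0.11 and 0.082). Heat shock genes went the other way, with a difference of -0.15 (0.11 and -0.032). Migration receptors split by genotype instead, at -0.080 without and 0.10 with doxorubicin, a difference of 0.18. These differences were not tested. Without clusters 0 to 2 the medians with the knockout label were 0.0044 for inhibitory receptors, 0.014 for memory and 0.043 for regulatory genes, while that of follicular helper genes was still 0.115.

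Shares of cells split as well. The CD8-like cells of clusters 5 and 8 were 0.875 times as frequent in the library labelled KO without doxorubicin and 1.08 times with it, so that the ratios differ by a factor of 1.24. Clusters 2 and 9 also carried Cd8b1, at 839 and 793 CPM, with Cd4 at 3.47 and 5.54 CPM. Cluster 9 took 11.2% of T-like cells in WT-DOX and 5.39% in KO-DOX. The split thus depends on whether clusters 2 and 9 are counted as CD8. By marker UMIs the ratio of CD8 to CD4 cells was lower with the KO label without (2.27 against 2.61) and with doxorubicin (2.64 against 3.22). That ratio is a different measure from the share of T-like cells, so it does not bear on the split directly. Cluster 9, led by Fos and Jun, was 1.46 times as frequent with doxorubicin in the control genotype and 0.82 times with the knockout label, a factor of 0.562. Cluster 0, led by mitochondrial genes and shallow, had ratios of 0.56 and 1.28, a factor of 2.29. Cluster 1, led by long nuclear transcripts, was 1.13 times as frequent in KO-CTRL as in WT-CTRL and 0.74 times in KO-DOX as in WT-DOX, a factor of 0.657. Clusters 0, 1 and 9 follow transcript states that handling of cells could also produce, and their borders moved between clustering settings (cluster 1 in KO-CTRL against WT-CTRL was 0.912 at Leiden resolution 0.5). None of these was tested either.

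The opposite movement of the activated lists may come in part from the numbers of activated cells. With T classes at equal proportions, the median over the 4 lists of the share kept of each response difference was 0.333. Follicular helper genes kept 0.4998, however, and regulatory genes 0.396. Values within classes were mixed: in Tfh-like cells, a cluster that also holds CD8 cells, follicular helper medians were -0.089 (inside the random range) with the control genotype and 0.22 with the knockout label, but memory medians -0.025 and -0.026, and in Treg-like cells inhibitory receptors had 0.049 and 0.30, but follicular helper genes 0.097 and 0.081. Doublets remain open: without cells holding both Cd4 and Cd8 UMIs the Tfh-like share ratio of KO over WT was 1.32 (1.14 to 1.53), against 1.34 in all cells, but only 0.339% of the cells were left out, so that the test decides nothing. Cell depth remains open too, since among cells of at least 2000 UMIs the ratio was 1.28 (1.096 to 1.49) and the interval just reached the bound of 1.1, which it had cleared before the clustering was redone in double precision, after results had been seen. A biological difference in Tfh-like cells between the genotypes under doxorubicin stays open and untested, because each group is 1 library.

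Several genes, 39 in all, stood at least 1.5 times above or below each other library with intervals apart and at least 10 CPM in 1 library, limits chosen after the data had been explored; of 21 such genes in WT-DOX, 20 were lower, among them histone and division genes such as Hist1h3b and Cenpe, and only Zbed5 was higher. A different mix of T cell classes could explain part: the median gene kept 0.567 of its log2 fold at equal proportions, but Zbed5 kept 1.01, Setbp1 1.01, Cdk5rap1 1.002 and Hnrnpa0 1.01. Chromosome segments from another mouse strain would put such genes near each other, and 35 pairs lay within 5 Mb against a median of 4 among random sets. Of these, however, 21 pairs were histone genes, 4 interferon-induced genes and 3 mitochondrial genes, which sit together in every mouse, 6 joined genes of different libraries, and 1 other pair was left. The pairs thus give no sign of such segments, but a segment holding 1 affected gene would make no pair, so strain stays open. No biological explanation was tested for Zbed5 or Setbp1, and treatment and genotype are carried by the same libraries.

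Of 41 ribosomal protein genes under 700 nt, 4 were lower in WT-DOX and the median of all was 0.058, while 4 of 7 under 400 nt were lower. A general loss of transcripts under 700 nt was argued against: other genes under 700 nt differed from longer ones by 0.049 log2. A lower level of all ribosomal protein genes was argued against by a median of 0.11 over those of at least 700 nt, and a different class mix by a kept share of 1.05 of the fold. Ribosomal transcripts under 400 nt had a median of -0.52 and 9 other genes of that length -0.088, so a technical effect on the shortest transcripts in this library may still contribute. With the knockout label the same ribosomal transcripts had a median of -0.098 under doxorubicin, 0 of 7 being lower, and an effect of doxorubicin in the control genotype cannot be separated with 1 library.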

How the results depend on the processing

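The alternatives said to be chosen after seeing the data are the clustering without interferon and heat shock genes, the other random seeds, and leaving out the cycling-like cluster, clusters 0 to 2 or mixed-marker cells. No paired analysis was possible because each group is 1 library and no label pairs the mice. Of 1012 list medians under the alternatives, 880 stayed within the width of their random lists, 113 moved further, some of them across 0, and 19 that had been outside their random range turned sign. Of 452 share ratios 375 stayed within their counting interval, 70 moved further and 7 turned to the other side of 1 although the intervals of the shares had been apart, and of 44 ratios of CD8 to CD4 cells 38 stayed and 6 moved. Of 2961 log2 folds of named genes over T-like cells, 2439 stayed within counting error, 507 moved further and 15 turned sign although the intervals had been apart, and within classes 670, 57 and 5 of 732. Median-of-ratios scaling, doublets kept and the stricter filter left all 92 list medians the same by this rule. Of 16 Trbv shares 6 moved. Thinning to 1500 UMIs lowered the median genes per cell by construction, to 818, 812, 819 and 825. The p53 targets kept a positive median with doxorubicin in both genotypes under every alternative (0.071 to 0.12 with the control genotype and 0.095 to 0.16 with the knockout label), and type I interferon genes a negative one. A positive p53 median was not particular to doxorubicin, since KO-CTRL against WT-CTRL had 0.071, above its random range. The Tfh-like share ratio stayed between 1.16 and 1.27 in KO-DOX against KO-CTRL and between 1.59 and 1.84 in KO-DOX against WT-DOX under every clustering. Some clusters had no cells of their own and so no value: cluster 0 at Leiden resolution 0.5 and with doublets kept, cluster 1 under the stricter filter, and gamma delta T-like cells at Leiden resolutions 0.5 and 2. Median-of-ratios scaling moved 10 gene folds. The number of cells limits what classes can show, as the Treg-like class held 371 to 489 cells in a library. What follows by alternative are the list medians and ratios that moved or turned and the genes counted as turned, with the comparison they belong to. Gene folds and Trbv shares that only moved are given as the counts above. Values are median log2 folds for lists, log2 folds for genes and ratios of shares, and "opposite" marks a change of sign, or for ratios of the side of 1. Except where the construction is named, the cause was not tested.

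Weighting every T class to the same proportion in each library moved the most values, and because the interferon-stimulated-like cluster is itself a class here, this weighting takes away part of any interferon difference by construction. The early T cell receptor median was 5.2e-05 (opposite), that of inhibitory receptor 0.0066 (opposite), that of memory -0.0079, that of regulatory -0.0048, that of helper cytokine 0.041 (opposite) and that of follicular helper -0.046 in WT-DOX against WT-CTRL. The type I interferon median was -0.13, that of S phase 0.019 (opposite), that of G2 and M phase -0.14 and that of PD-1 pathway -0.066 in WT-DOX against WT-CTRL. The median of cytotoxic genes was 0.064, that of type I interferon -0.14 and that of interferon gamma 0.026 (opposite) in KO-DOX against KO-CTRL. Inhibitory receptor genes stood at -0.073 (opposite), memory at -0.050 (opposite), regulatory at -0.11 (opposite), type I interferon at 0.21, interferon gamma at 0.092 and S phase at 0.0088 in KO-CTRL against WT-CTRL. G2 and M phase genes stood at -0.031 (opposite), oxidative phosphorylation at 0.050 and mitochondrial at -0.0090 in KO-CTRL against WT-CTRL. The naive median was -0.00068, that of cytotoxic 0.016, that of inhibitory receptor 0.11, that of memory -0.031 (opposite), that of regulatory -0.012 (opposite) and that of helper cytokine -0.037 (opposite) in KO-DOX against WT-DOX. The follicular helper median was 0.25, that of type I interferon 0.19, that of DNA repair 0.036, that of S phase 0.0023, that of G2 and M phase 0.064 and that of heat shock -0.048 in KO-DOX against WT-DOX. The ferroptosis median was -0.0045 (opposite), that of glycolysis 0.074, that of oxidative phosphorylation 0.020, that of mitochondrial -0.50, that of migration 0.013 and that of PD-1 pathway 0.042 in KO-DOX against WT-DOX. Pclaf stood at 0.010 (opposite) in WT-DOX against WT-CTRL. Mki67 stood at -0.090 (opposite) in KO-CTRL against WT-CTRL. Gzmb stood at -0.28 (opposite) and Pclaf at -0.061 (opposite) in KO-DOX against WT-DOX.

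Giving each cell the same weight lets the many cells with few UMIs count as much as large activated or dividing cells. The median of inhibitory receptor genes was 0.011 (opposite), that of memory -0.044, that of regulatory -0.036, that of type I interferon -0.13, that of interferon gamma 0.031 (opposite) and that of S phase -0.097 in WT-DOX against WT-CTRL. The median of mitochondrial genes was -0.18 and that of PD-1 pathway -0.073 in WT-DOX against WT-CTRL. Naive genes stood at 0.0041 (opposite), early T cell receptor at 0.024 (opposite), cytotoxic at 0.17, inhibitory receptor at 0.24, memory at 0.16 and regulatory at 0.17 in KO-DOX against KO-CTRL. Helper cytokine genes stood at 0.18, follicular helper at 0.27, type I interferon at -0.24, S phase at 0.089, G2 and M phase at 0.050 and mitochondrial at -0.47 in KO-DOX against KO-CTRL. Migration genes stood at 0.10 and PD-1 pathway at 0.14 in KO-DOX against KO-CTRL. The inhibitory receptor median was -0.024 (opposite), that of regulatory 0.086, that of interferon gamma 0.21, that of DNA repair -0.029 (opposite), that of S phase -0.030 (opposite) and that of G2 and M phase -0.037 (opposite) in KO-CTRL against WT-CTRL. The glycolysis median was -0.0058 (opposite) and that of mitochondrial -0.27 in KO-CTRL against WT-CTRL. The median of naive genes was -0.031, that of cytotoxic 0.22, that of regulatory 0.38, that of follicular helper 0.69, that of S phase 0.17 and that of G2 and M phase 0.46 in KO-DOX against WT-DOX. The median of oxidative phosphorylation genes was 0.057 in KO-DOX against WT-DOX. mt-Cytb stood at -0.041 (opposite) in WT-DOX against WT-CTRL. Cd4 stood at 0.018 (opposite) and Itgb1 at 0.12 (opposite) in KO-DOX against KO-CTRL. Mki67 stood at -0.33 (opposite) and Rrm2 at -0.14 (opposite) in KO-CTRL against WT-CTRL. Gzma stood at -0.39 (opposite) among Tfh-like cells in KO-DOX against KO-CTRL.

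Leaving out the cycling-like cluster, an alternative chosen after seeing the data, takes away the cells that carry division transcripts by construction. The inhibitory receptor median was -0.026, that of memory -0.071, that of regulatory -0.044, that of S phase -0.022 and that of G2 and M phase -0.13 in WT-DOX against WT-CTRL. The median of cytotoxic genes was 0.20, that of helper cytokine -0.044 (opposite) and that of S phase 0.056 in KO-DOX against KO-CTRL. Memory genes stood at 0.011, helper cytokine at -0.059 (opposite), DNA repair at -0.013 (opposite), S phase at -0.0018 (opposite), G2 and M phase at -0.069 (opposite) and oxidative phosphorylation at 0.048 in KO-CTRL against WT-CTRL. The naive median was -0.027, that of inhibitory receptor 0.21, that of memory 0.15, that of DNA repair 0.048, that of S phase 0.053 and that of G2 and M phase 0.058 in KO-DOX against WT-DOX. The glycolysis median was 0.084 and that of oxidative phosphorylation 0.049 in KO-DOX against WT-DOX. Klrc1 stood at 0.0094 (opposite) and Hspd1 at 0.0066 (opposite) in WT-DOX against WT-CTRL. Ifng stood at -0.040 (opposite) in KO-DOX against KO-CTRL. Mki67 stood at -0.16 (opposite) and Rrm2 at -0.12 (opposite) in KO-CTRL against WT-CTRL. Tpx2 stood at -0.0075 (opposite) in KO-DOX against WT-DOX.

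Leaving out clusters 0 to 2, also chosen after seeing the data, shrinks the total to which shares are referred, and cluster 0 and cluster 1 then have no value. Mitochondrial genes stood at -0.0092 in WT-DOX against WT-CTRL. The cytotoxic median was 0.070, that of inhibitory receptor 0.0044, that of memory 0.014, that of regulatory 0.043, that of S phase -0.033 (opposite) and that of G2 and M phase -0.038 (opposite) in KO-DOX against KO-CTRL. The integrated stress median was -0.0042 (opposite) and that of apoptosis 0.059 in KO-DOX against KO-CTRL. The median of mitochondrial genes was -0.041 in KO-CTRL against WT-CTRL. Naive CD4-like had a share ratio of 0.977 (opposite), clusters 5 and 8 of 0.985 (opposite), all CD8-like of 1.002 and all CD4-like of 0.953 (opposite) in WT-DOX against WT-CTRL. For naive CD4-like the share ratio was 0.951 (opposite), for clusters 5 and 8 1.19, for all CD8-like 1.17 and for all CD4-like 0.984 (opposite) in KO-DOX against KO-CTRL.

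A pseudocount of 5 CPM in place of 1 pulls genes with low counts toward 0 by construction. The median of type I interferon genes was -0.16 and that of G2 and M phase -0.31 in WT-DOX against WT-CTRL. Type I interferon genes stood at -0.23 in KO-DOX against KO-CTRL. The type I interferon median was 0.37 in KO-CTRL against WT-CTRL. The median of follicular helper genes was 0.46, that of type I interferon 0.23, that of S phase 0.25 and that of G2 and M phase 0.56 in KO-DOX against WT-DOX.

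Taking only list members above 20 CPM changes which genes enter a median. G2 and M phase genes stood at -0.32 in WT-DOX against WT-CTRL. The helper cytokine median was -0.051 (opposite), that of type I interferon -0.23 and that of p53 0.16 in KO-DOX against KO-CTRL. The median of type I interferon genes was 0.35 in KO-CTRL against WT-CTRL. Early T cell receptor genes stood at 0.014 (opposite) and integrated stress at 0.11 in KO-DOX against WT-DOX.

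Taking every member with any UMI brings in genes with very few counts. The cytotoxic median was -0.093 in WT-DOX against WT-CTRL. The median of inhibitory receptor genes was 0.030, that of helper cytokine 0.14 and that of integrated stress 0.035 in KO-DOX against KO-CTRL. Interferon gamma genes stood at 0.11 in KO-CTRL against WT-CTRL. The inhibitory receptor median was 0.23 and that of helper cytokine 0.19 in KO-DOX against WT-DOX.

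Keeping the cells scored as doublets moved shares, and genes seen in few Tfh-like cells. In share, cluster 9 had a ratio of 1.33 in WT-DOX against WT-CTRL. Clusters 5 and 8 had a share ratio of 1.15, cluster 1 of 0.685, cluster 9 of 0.950 and all CD8-like of 1.15 in KO-DOX against KO-CTRL. For clusters 5 and 8 the share ratio was 0.954, for cluster 1 1.01 and for all CD8-like 0.965 in KO-CTRL against WT-CTRL. In share, cluster 1 had a ratio of 0.863 and cluster 9 of 0.657 in KO-DOX against WT-DOX. The CD8 to CD4 ratio of ratios was 1.09 in KO-DOX against KO-CTRL. The CD8 to CD4 ratio of ratios was 0.921 in KO-CTRL against WT-CTRL. Gzma stood at -0.41 (opposite) and Gzmb at -0.73 (opposite) among Tfh-like cells in WT-DOX against WT-CTRL. Gzmb stood at -0.73 (opposite) among Tfh-like cells in KO-CTRL against WT-CTRL. Ly6c2 stood at 0.020 (opposite) among Tfh-like cells in KO-DOX against WT-DOX.

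The stricter filter drops cells with few detected genes. In share, naive CD4-like had a ratio of 0.954 (opposite) and all CD4-like of 0.939 (opposite) in WT-DOX against WT-CTRL. Naive CD4-like had a share ratio of 0.887 (opposite), cluster 0 of 0.793 (opposite) and all CD4-like of 0.937 (opposite) in KO-DOX against KO-CTRL. For cluster 0 the share ratio was 0.565 in KO-CTRL against WT-CTRL. In share, cluster 0 had a ratio of 0.751 (opposite) and all CD4-like of 1.05 in KO-DOX against WT-DOX. The CD8 to CD4 ratio of ratios was 1.38 in KO-DOX against KO-CTRL.

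Coarser clustering at resolution 0.5 redrew the borders of the classes. For cluster 1 the share ratio was 0.698 in WT-DOX against WT-CTRL. In share, clusters 5 and 8 had a ratio of 1.18, cluster 1 of 0.602 and all CD8-like of 1.18 in KO-DOX against KO-CTRL. Clusters 5 and 8 had a share ratio of 0.940, Tfh-like of 1.13, cluster 1 of 0.912 (opposite) and all CD8-like of 0.950 in KO-CTRL against WT-CTRL. The CD8 to CD4 ratio of ratios was 0.939 in KO-CTRL against WT-CTRL.

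Finer clustering at resolution 2 moved 1 share ratio. In share, cluster 1 had a ratio of 0.609 in KO-DOX against KO-CTRL.

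Clustering on 1000 variable genes redrew some borders. Clusters 5 and 8 had a share ratio of 0.986 (opposite) and cluster 0 of 0.744 in WT-DOX against WT-CTRL. For cluster 1 the share ratio was 0.635 and for cluster 9 0.962 in KO-DOX against KO-CTRL. In share, cluster 0 had a ratio of 0.747 and cluster 1 of 0.946 (opposite) in KO-CTRL against WT-CTRL. Cluster 0 had a share ratio of 1.26 and cluster 9 of 0.656 in KO-DOX against WT-DOX.

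Counting CD8 and CD4 cells by marker UMIs, without clusters, departed as follows. The CD8 to CD4 ratio of ratios was 1.23 in WT-DOX against WT-CTRL. The CD8 to CD4 ratio of ratios was 0.819 in KO-DOX against WT-DOX.

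A different random seed for the clustering, chosen after seeing the data, shifted cells between neighbouring clusters. Cluster 0 had a share ratio of 0.767, cluster 1 of 0.756 and cluster 9 of 1.33 in WT-DOX against WT-CTRL. For cluster 0 the share ratio was 1.08 and for cluster 1 0.608 in KO-DOX against KO-CTRL. In share, cluster 0 had a ratio of 0.819, cluster 1 of 0.917 (opposite) and cluster 9 of 0.752 in KO-CTRL against WT-CTRL. Cluster 9 had a share ratio of 0.422 in KO-DOX against WT-DOX.

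Another seed, likewise chosen after seeing the data, did the same. For clusters 5 and 8 the share ratio was 0.984 (opposite), for cluster 0 0.721, for cluster 1 0.764 and for all CD8-like 1.01 in WT-DOX against WT-CTRL. In share, cluster 9 had a ratio of 0.914 in KO-DOX against KO-CTRL. Clusters 5 and 8 had a share ratio of 0.827, cluster 0 of 0.761, cluster 1 of 1.01, cluster 9 of 0.981 and all CD8-like of 0.852 in KO-CTRL against WT-CTRL. For cluster 0 the share ratio was 1.19 and for cluster 9 0.629 in KO-DOX against WT-DOX.

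Clustering without interferon and heat shock genes, chosen after seeing the data, dissolves the interferon-stimulated-like cluster into other classes. In share, naive CD4-like had a ratio of 0.987 (opposite) and clusters 5 and 8 of 0.992 (opposite) in WT-DOX against WT-CTRL. Naive CD4-like had a share ratio of 0.940 (opposite), clusters 5 and 8 of 1.20, cluster 1 of 0.400, cluster 9 of 0.971, all CD8-like of 1.19 and all CD4-like of 0.981 (opposite) in KO-DOX against KO-CTRL. For cluster 1 the share ratio was 1.45 and for cluster 9 0.962 in KO-CTRL against WT-CTRL. In share, cluster 1 had a ratio of 0.655, cluster 9 of 0.644 and all CD4-like of 1.06 in KO-DOX against WT-DOX.

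Leaving out cells with both Cd4 and Cd8 UMIs, chosen after seeing the data, moved 1 list median and 13 gene folds. G2 and M phase genes stood at 0.72 in KO-DOX against WT-DOX.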

Other observations

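No test in this part was planned or run beyond the values given, and the choice of T cell receptor segments and of single-cell examples was made after seeing the data.

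T cell receptor beta segments give a coarse view of clonal skew. Trbv12-2 made up 16.8% of Trbv UMIs in effector or memory CD8-like cells of WT-CTRL against 10.2% in clusters 5 and 8, 13.97% against 9.06% in WT-DOX, 13.2% against 10.1% in KO-CTRL and 11.6% against 9.19% in KO-DOX. Among cells with any Trbv UMI, it was seen in 110 of 393 against 686 of 2773 in WT-CTRL and 109 of 434 against 589 of 2784 in WT-DOX. The counts were 111 of 395 against 524 of 2416 in KO-CTRL and 83 of 361 against 555 of 2531 in KO-DOX. In Tfh-like cells Trbv3 made up 10.07% in WT-CTRL, 8.65% in WT-DOX, 12.6% in KO-CTRL and 12.8% in KO-DOX, against 7.80%, 7.43%, 7.25% and 7.36% in naive CD4-like cells of the same libraries. UMIs of 1 cell share 1 receptor, so these shares count molecules and not clones.

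Cells gated by marker UMIs gave a ratio of CD8 to CD4 cells of 2.61 in WT-CTRL, 3.22 in WT-DOX, 2.27 in KO-CTRL and 2.64 in KO-DOX. By these values CD8 cells outnumbered CD4 cells in each library, whereas in the named clusters CD4-like cells outnumbered CD8-like cells. The named clusters held 29.2%, 30.8%, 26.1% and 33.0% CD8-like and 36.6%, 36.6%, 38.1% and 40.5% CD4-like cells among T-like cells. These CD8-like shares leave out clusters 2 and 9, which carried Cd8b1 at 839 and 793 CPM with little Cd4. The CD4-like shares leave out cluster 1, which carried Cd4 at 120 CPM and made up 10.5%, 8.80%, 11.9% and 6.55% of T-like cells. Cluster 2 made up 5.02%, 5.07%, 6.56% and 5.03% of T-like cells and cluster 9 7.65%, 11.2%, 6.57% and 5.39%. Whether CD8 or CD4 cells are more frequent thus depends on how cells are called. Among cycling-like cells the gated ratio was 1.81, 1.40, 1.19 and 1.44. Gamma delta T-like cells, led by Trdv4 and Il17a, made up 0.448%, 0.316%, 0.261% and 0.466% of T-like cells, and the interval of the ratio of KO-DOX to KO-CTRL, 1.78 (1.14 to 2.78), left out 1 although the intervals of the shares overlapped. B- or plasma-like cells made up 0.398%, 0.348%, 0.512% and 0.649% of kept cells, and KO-DOX had 1.87 times the share of WT-DOX (1.27 to 2.75), although sorting for T cells sets this share.

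Some large folds within classes rest on few cells. In Treg-like cells of KO-DOX, Ccl4 came from 6 cells, with 105 UMIs in 1 of them. In Tfh-like cells of KO-DOX, Il17a came from 5 cells, with 84 UMIs in 1 of them. Gzma in Tfh-like cells came from 11 cells in WT-DOX and 5 in WT-CTRL, and Cxcl2 in Treg-like cells from 19 in each.

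Transcripts typical of other cells were summed over T-like cells. Free RNA, doublets that stayed and the T-like cells themselves can all add to these sums and were not told apart. In WT-CTRL, WT-DOX, KO-CTRL and KO-DOX, B cell markers stood at 258, 271, 248 and 285 CPM, dendritic cell markers at 193, 211, 227 and 223 CPM, monocyte or macrophage markers at 172, 160, 174 and 173 CPM, stromal markers at 112, 107, 101 and 97.1 CPM, plasma cell markers at 38.0, 35.5, 35.9 and 37.9 CPM, and tumour epithelium markers at 12.6, 8.25, 7.28 and 7.12 CPM. Neutrophil, mast cell or basophil, erythroid and platelet markers each stood at no more than 1.17 CPM in any library.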
